A study of Mus musculus with 6 samples.

How the data were processed

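The series holds 6 mRNA-seq libraries of mouse left ventricle after TAC, 3 with anti-IgG and 3 with anti-PD-1 antibody. Per the labels' protocols, RNA quality was assessed on a Bioanalyzer and on agarose gels, and enriched mRNA was fragmented and converted to cDNA with a NEBNext Ultra kit; the labels do not say that the kit marked strand. The authors deposited a table of raw read counts per gene; featureCounts and the mm10 build are named in the submitters' processing notes, without versions, and the aligner is not given in the sources used here. The count table has 54929 rows, of which 54409 carry gene identifiers found in the GENCODE M21 names and 397 are unannotated transcripts without a gene name. Whether counting used strand is not stated; at 4 unannotated loci listed on both strands, all reads stood on the minus strand. The authors also deposited FPKM values. In genes with at least 1000 reads these equal the count divided by the authors' gene length and by 1 constant per library, within 4.9e-08 percent; that constant is 0.953 to 1.15 times the library's summed counts, so the FPKM were scaled between libraries by a step that is not given in the sources used here. The gene length column of the deposited table is in bp and can far exceed the length of a coding transcript. For Cox6c it is 3567 bp, against 364 bp of coding sequence and 3' UTR in its longest GENCODE transcript that has both. Both tables held the same 6 samples.

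Summed counts per library were 18063344 to 21093163. The 10 most counted genes took 32.8 ± 3.67% of the reads with anti-PD-1 and 33.4 ± 4.77% with anti-IgG (mean ± SD, n = 3 each). All 6 libraries had a male pattern: Ddx3y had 1261 to 2687 reads and Xist 0 to 17. Libraries of a group differed by far more than sampling noise, with a chi-square statistic per degree of freedom of 47.3 to 76.1 between libraries of the same group. This compares them with counting error alone, so it does not show that they came from separate animals. Each library was counted as its own replicate, as labelled. Exact Poisson intervals (95%) of low counts cover counting error only.

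Counts were tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr, libraries scaled by TMM, and groups compared with the quasi-likelihood F test (glmQLFit with robust=TRUE), 2-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The count of genes with an absolute log2 fold change of at least 1 is given beside it. The SE of a log2 fold change is its size divided by the square root of its F statistic. Before the data were examined, 32 gene lists with 514 members were fixed, for immune cells and programmes, matrix, hypertrophy, contraction, metabolism, cell death and stress, the other cell types of a ventricle, other tissue that a dissection could include, and RNA quality, handling and hour of collection. The 30 lists with at least 3 tested members were compared with all other genes by camera (limma 3.58.1) with a preset inter-gene correlation of 0.01; camera with an estimated correlation and fry were run beside it. With the estimated correlation 0 lists passed, and the lowest adjusted p was 0.996; by fry 0 passed either, and the lowest was 0.0668. Members were also counted with edgeR p-values adjusted over the list alone.

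The genes named were set by a rule fixed at the same time: Pdcd1, Gzmb, Cd8a, Cd8b1 and Prf1; the 10 largest rises and 10 largest falls among genes past the threshold with a mean log2 CPM of at least 1, an informative symbol and no overlap between the 3 values of each group; and in each list the 2 tested members with the smallest unadjusted p, plus Nppa, Nppb, Myh7, Myh6, Col1a1, Col3a1 and Postn. Other list members that passed are named beside their list's count, and were chosen after their values were seen. Results of a few genes that the rule names are not reported. Chance gives 10% of genes without overlap between 3 and 3 values; 41.0% of the tested genes had none.

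The alternatives fixed beforehand were RLE and upper quartile scaling, no count filter, a stricter filter (at least 1 CPM in at least 3 libraries), DESeq2 1.42.0, limma-voom, robust=FALSE, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) and on genes with an FPKM of at least 1 in at least 3 libraries, the replicate number as a block, mitochondrially encoded and haemoglobin genes left out, other thresholds, and each library left out in turn. After the data were seen, 4 corrections were added. Each took out a library's trend of log2 CPM (prior count 2), taken about the gene's mean over the 6 libraries. The trend was fitted on the authors' gene length, on GC content, on coding and 3' UTR lengths (called the transcript length trend), or on these and GC content. Coding and 3' UTR lengths were those of the longest GENCODE M21 transcript that has both. The fits used natural splines of 5 degrees of freedom and were entered as an offset. GC content was available for 99.0% of the tested genes and both transcript lengths for 99.6% of the coding genes tested. Genes without both lengths, among them noncoding, unannotated and mitochondrially encoded ones, were given the median lengths and a shared term. The transcript length correction therefore did not use the length of those genes. A trend that differs between the groups is removed whatever its origin.

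The gene test was tested on simulated counts with the means, dispersions and library sizes of these data. In 14570 genes of the simulated anti-PD-1 against anti-IgG comparison, 200 were changed: 44.4% of those with a log2 fold change of 1 and 92.9% of those with 2 were recovered, with 19 false calls among 155. A list shifted by -0.7 in 14545 simulated genes, the interferon response list, was the only 1 of 30 lists called. Simulated genes were drawn independently of one another, so this does not test camera where the genes of a list vary together. In the real counts the estimated correlation of that list was 0.35, against the preset 0.01. A simulated length slope of 0.3 was 0.0106 after the length trend was removed.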

Results

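Gene expression was measured by mRNA sequencing of left ventricles from wild-type C57BL/6 mice after transverse aortic constriction (TAC), a surgical narrowing of the aorta that places the left ventricle under pressure overload. In 1 group of 3 libraries the mice had been given an anti-IgG control antibody, and in the other group of 3 an antibody against PD-1, an inhibitory receptor of activated T cells that is encoded by Pdcd1. Both antibodies were injected intraperitoneally at 10 mg/kg every 3 days, starting 2 weeks after surgery, and all 6 samples carry a time label of 5 weeks. The libraries held 18063344 to 21093163 counted reads each. Transcripts of the mitochondrial genome took 32.6 ± 3.43% of the counts with anti-PD-1 and 33.3 ± 5.24% with anti-IgG (mean ± SD, n = 3 each; exact 2-sided permutation p = 0.8, with 0.1 the smallest p that 3 against 3 libraries allow). The labels do not say whether libraries came from separate animals, so p-values measure only the spread between these samples. Levels below are TMM-scaled CPM of the counted reads, given as mean ± SD over the 3 libraries of a group, and log2 fold changes are anti-PD-1 against anti-IgG with their standard error (SE).

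The comparison asks what PD-1 blockade changes in the pressure-overloaded ventricle. With anti-PD-1, 3118 of 14807 tested genes changed, of which 1525 rose and 1593 fell (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 1424 of them changed by at least 1 on the log2 scale, 495 upwards and 929 downwards. In 6070 of the 14807 tested genes (41.0%) the values of the groups did not overlap, which chance gives in 10% of genes. Among the largest rises was Hipk2, which encodes a nuclear serine/threonine kinase (chromosome 6, 38694390 to 38876165 in mm10): it stood at 92.2 ± 21.1 CPM with anti-PD-1 and 7.29 ± 1.67 CPM with anti-IgG, a log2 fold change of 3.66 (SE 0.25, edgeR adjusted p = 0.000142). Slc8a1, the cardiac sodium-calcium exchanger (chromosome 17, 81388691 to 81649607), rose from 19.3 ± 7.24 to 142.3 ± 21.99 CPM (log2 fold change 2.88, SE 0.28, edgeR adjusted p = 0.00123). Ppara, a nuclear receptor that drives genes of fatty acid oxidation, rose from 3.54 ± 1.60 to 30.8 ± 17.9 CPM (log2 fold change 3.12). Gpam, which catalyses the initial step of triglyceride synthesis, rose by 3.16 on the log2 scale, Pdpr, a regulatory subunit of pyruvate dehydrogenase phosphatase, by 3.19, and Nt5c1a, a nucleotidase that forms adenosine from AMP, by 3.77 (edgeR adjusted p from 0.00206 to 0.00737 for these 4 genes). Pm20d2 (3.27), Uprt (2.73) and Zbtb16 (2.59) were also among the 10 largest rises.

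Among the 10 largest falls was Cox7a1, the muscle form of a cytochrome c oxidase subunit (chromosome 7, 30184144 to 30186078), which fell from 202 ± 61.4 to 27.5 ± 16.9 CPM (log2 fold change -2.88, SE 0.50, edgeR adjusted p = 0.0103). Ndufa3 of respiratory complex I had a log2 fold change of -2.43, the ribosomal protein gene Rpl38 of -2.47, and Snrpf and Snrpg, which encode Sm proteins of the spliceosome, of -2.93 and -2.58. Naa38 (-2.57), Pin4 (-2.52) and the chemokine gene Ccl27a (-2.52) also fell. Ccl27a has near-identical copies that can share its reads, so its count is uncertain. Isg15, an interferon-induced ubiquitin-like protein, fell from 6.22 ± 3.46 to 1.18 ± 0.23 CPM, and the long noncoding RNA Neat1, a scaffold of nuclear paraspeckles (chromosome 19, 5824708 to 5845478), fell from 278 ± 104 to 53.4 ± 0.73 CPM (log2 fold change -2.38, SE 0.27, edgeR adjusted p = 0.00199).

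**Figure D1:**
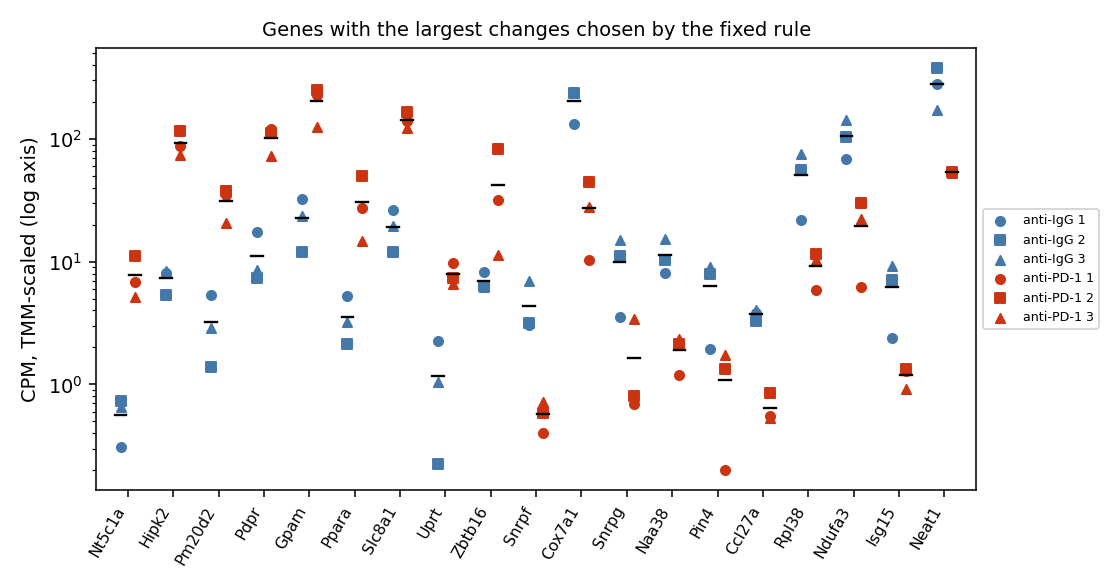
CPM on a log axis of genes among the 10 largest rises and 10 largest falls under the rule fixed beforehand; each point is 1 library and black bars are means over 3 libraries. In all genes drawn the 3 anti-PD-1 values lie outside the range of the 3 anti-IgG values, which was a condition of the rule; Hipk2 runs from 5.37 to 8.36 CPM with anti-IgG and from 74.0 to 115 CPM with anti-PD-1.

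The number of changed genes rested on single libraries. It was 532 without anti-IgG library 2, 969 without anti-PD-1 library 1, 1564 without anti-IgG library 3 and 1766 without anti-PD-1 library 3. It stayed within 1.5 times of 3118 without either of the other 2 libraries. The rises of Hipk2, Slc8a1, Ppara, Gpam, Pdpr, Nt5c1a and Pm20d2 and the falls of Cox7a1, Snrpf, Naa38, Ccl27a and Neat1 stayed past the threshold without any 1 library. The calls of Rpl38 (edgeR adjusted p = 0.0514) and Isg15 (0.0502) ended without anti-IgG library 2 and that of Uprt (0.0528) without anti-IgG library 3. Ndufa3 lost its call without anti-IgG library 2 or 3 or anti-PD-1 library 3 (0.0521 to 0.0723). The call of Snrpg ended without anti-IgG library 2 or 3 or anti-PD-1 library 1 or 2 (0.103 to 0.131), and that of Zbtb16 without any 1 anti-IgG library or anti-PD-1 library 1 (0.0629 to 0.113). Pin4 lost its call without any 1 library other than anti-IgG library 1 (0.0599 to 0.126). Without the count filter Ndufa3 (0.0994) and Zbtb16 (0.166) did not pass. Upper quartile scaling put the median log2 fold change of all tested genes at -0.12, against -0.03 with TMM, and 36.8% of the changed genes rose with it, against 48.9%.

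Long genes were higher and short genes lower with anti-PD-1. Among the 1481 shortest tested genes by the authors' gene length, of 57 to 1407 bp, 31 rose and 473 fell, with a median log2 fold change of -0.81. Among the 1481 longest, of 9594 to 123179 bp, 451 rose and 15 fell, with a median of 0.45. Across the tested genes, which are not independent replicates, the log2 fold change had a Spearman rank correlation of 0.49 with gene length. In 13037 coding genes it was 0.48 with the length of the 3' UTR and 0.44 with the coding length, and across the tested genes -0.23 with GC content. Deviations from each gene's 6-library mean correlated with gene length at 0.41, 0.30 and 0.35 in anti-PD-1 libraries 1 to 3 and at -0.19, -0.38 and -0.49 in anti-IgG libraries 1 to 3 (exact 2-sided permutation p = 0.1, the smallest possible). Since they sum to 0 in each gene, these values are tied to one another and do not show a trend in any library alone. When each library's trend on coding and 3' UTR length was removed, a setting chosen after the trend was seen, 756 genes were past the threshold, 449 higher and 307 lower. Of these 591 were among the 3118 in the same direction. The changes of Hipk2, Slc8a1, Ppara, Gpam, Pdpr, Nt5c1a, Neat1, Cox7a1 and Rpl38 remained past the threshold there, with log2 fold changes of 2.96, 2.13, 3.02, 2.64, 2.79, 4.37, -2.02, -1.82 and -1.25, and so did those of Pm20d2, Uprt, Snrpf, Naa38 and Ccl27a. Those of Zbtb16, Snrpg, Pin4, Ndufa3 and Isg15 did not (edgeR adjusted p from 0.0711 to 0.159), with log2 fold changes of 2.21, -1.69, -1.515, -1.44 and -1.41. Neat1 is noncoding, so that correction did not use its own length. With the trend on the authors' gene length removed, Neat1 was at -2.87 (edgeR adjusted p = 0.000368).

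**Figure D2:**
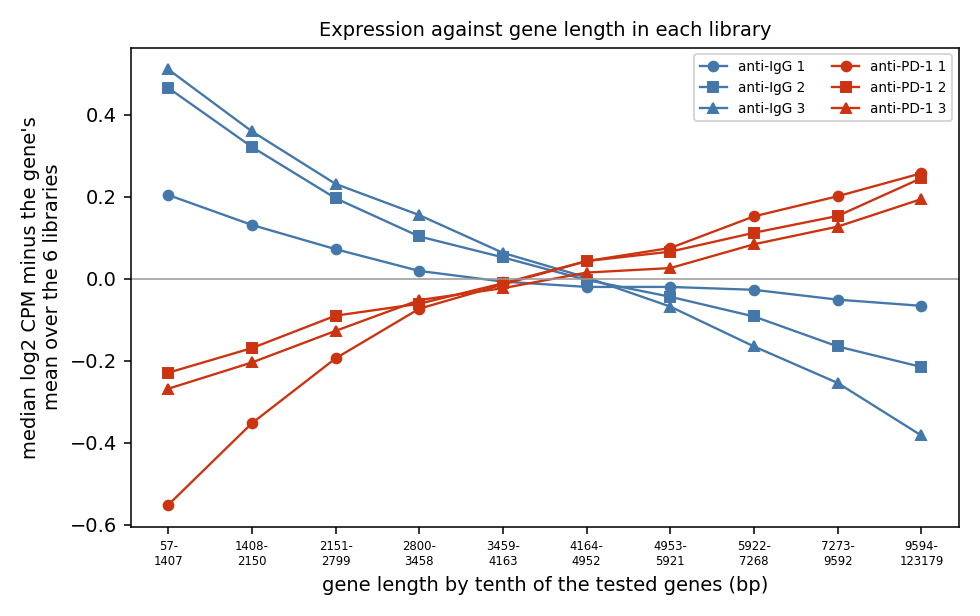
Median over genes of log2 CPM minus the gene's mean over the 6 libraries (y axis), for 10 groups of the tested genes by gene length in bp (x axis); each line is 1 library. In the shortest genes the anti-IgG libraries lie at 0.20 to 0.51 and the anti-PD-1 libraries at -0.55 to -0.23, and in the longest genes the order of the groups is turned, at -0.38 to -0.07 and 0.19 to 0.26.

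The transcripts named in the study's title were close to the detection limit of whole-ventricle RNA. Pdcd1 (chromosome 1, 94038305 to 94052553) had 6 reads in the 3 anti-PD-1 libraries together and 7 in the 3 anti-IgG libraries, a ratio of read shares of 0.806 (95% exact Poisson interval 0.224 to 2.80). Gzmb, which encodes the cytotoxic protease granzyme B (chromosome 14, 56258838 to 56262260), had 19 reads with anti-PD-1 (10, 7 and 2 in libraries 1 to 3) and 12 with anti-IgG (3, 5 and 4), a ratio of 1.49 (0.686 to 3.36; exact 2-sided permutation p = 0.6). Prf1, the pore-forming protein perforin, had 20 and 19 reads, a ratio of 0.990 (0.502 to 1.96). These 3 genes fell below the count filter and a difference was not detectable at this depth. The intervals cover counting error only. Of the chains of the CD8 co-receptor, Cd8a had 58 reads with anti-PD-1 and 31 with anti-IgG (log2 fold change 0.85, SE 0.48, edgeR adjusted p = 0.216). Cd8b1 had 19 and 32 (-0.80, SE 0.58, edgeR adjusted p = 0.343). Neither passed the threshold, and their values lay on opposite sides of 0. Their ratios of read shares, with intervals for counting error only, were 1.76 (1.12 to 2.82) for Cd8a and 0.558 (0.299 to 1.02) for Cd8b1.

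Of the 20 genes of T cell receptor and identity, 8 were tested: 2 fell, 0 rose and 6 did not pass, and the counts were the same adjusted over the list alone. Cd2, an adhesion receptor of T cells and natural killer cells, had 1, 2 and 3 reads in the anti-PD-1 libraries and 13, 14 and 13 in the anti-IgG libraries (log2 fold change -2.72, SE 0.66, edgeR adjusted p = 0.0178). Trac, the constant region of the T cell receptor alpha chain, had a log2 fold change of -1.32 (SE 0.42, edgeR adjusted p = 0.0471). The list as a whole had a median of -0.63 and did not pass (camera adjusted p = 0.558). Both calls ended with the transcript length trend removed (edgeR adjusted p = 0.082 for Cd2 and 0.40 for Trac), where Cd2 was at -2.13 and Trac at -0.595. Cd2 also lost its call without anti-IgG library 2 or 3 or anti-PD-1 library 1 (0.0519 to 0.0797), and Trac without any 1 of the 6 libraries (0.0533 to 0.152). Trac did not pass without the count filter (0.0611), by DESeq2 (0.0545), or without mitochondrially encoded and haemoglobin genes (0.0508). Only 3 of 18 cytotoxic effector genes were tested and 0 changed, Ccl5 with a log2 fold change of -0.35 and Il2rb with 0.15 (median 0.12, mean -0.03, camera direction down, adjusted p = 0.984). Of the 12 immune checkpoint genes, 7 were tested and 0 changed, with Ctla4 at -1.03 (SE 0.55) and Lag3 at -0.89 (SE 0.52) and a list median of -0.33 (camera adjusted p = 0.752). In the 13 fixed lists where edgeR called 0 of 101 tested members, these included, 8 members had an unadjusted p under 0.05, DESeq2 called 2 and limma-voom 0.

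Genes of the interferon response were lower with anti-PD-1. All 25 were tested: 9 fell, 0 rose and 16 did not pass, and 12 fell when adjusted over the list alone. The list's median log2 fold change was -0.66 (camera adjusted p = 8.58e-05 with the preset correlation; adjusted p = 0.996 with an estimated correlation). Irf7, a transcription factor that amplifies type I interferon responses, fell from 21.6 ± 7.36 to 8.23 ± 0.14 CPM (log2 fold change -1.39, SE 0.26, edgeR adjusted p = 0.00827). Cxcl9, a chemokine gene induced by interferon gamma, fell from 14.1 ± 2.52 to 5.76 ± 0.85 CPM (log2 fold change -1.29, SE 0.23, edgeR adjusted p = 0.00754). Irf1 (-0.80), Ifit3 (-0.77), Bst2 (-1.79), Rtp4 (-0.82), Xaf1 (-1.18) and Isg15 were among the other members that fell. Irf7 and Cxcl9 stayed past the threshold without any 1 library and with the transcript length trend removed. After that correction the list's median was -0.53 (camera adjusted p = 2.72e-05; adjusted p = 0.869 with an estimated correlation) and 4 members were past the threshold. By fry, which tests whether a list's genes move one way on balance, the list did not pass (adjusted p = 0.119).

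The 18 antigen presentation genes showed 8 falls, 0 rises and 10 that did not pass, with 10 falls adjusted over the list alone, and a median of -0.60 (camera adjusted p = 6.75e-04; adjusted p = 0.996 with an estimated correlation). Psmb9, a catalytic subunit of the immunoproteasome, fell from 13.5 ± 1.23 to 5.61 ± 0.87 CPM (log2 fold change -1.26, SE 0.22), and the nonclassical class I gene H2-T23 from 42.9 ± 3.17 to 24.2 ± 2.60 CPM (-0.82, SE 0.17; edgeR adjusted p = 0.00694 and 0.0110). The class II genes H2-Aa (-0.84), H2-Ab1 (-0.61) and H2-Eb1 (-0.85) fell as well. H2 genes resemble one another and can share reads. After the transcript length correction the list's median was -0.22 and its call ended (camera adjusted p = 0.166), as it did with the gene length trend removed (0.0506). None of its members was past the threshold by edgeR with transcript length corrected. Without anti-IgG library 2 the call of H2-T23 ended (edgeR adjusted p = 0.056).

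Of 14 tested B cell and plasma cell genes (15 listed), 5 fell, 0 rose and 9 did not pass, with 6 falls adjusted over the list alone. The list's median was -1.07 (camera adjusted p = 0.00287; adjusted p = 0.996 with an estimated correlation). Cd79a, a signalling chain of the B cell receptor, had 0, 2 and 3 reads with anti-PD-1 and 17, 10 and 52 with anti-IgG (log2 fold change -3.91, SE 0.88, edgeR adjusted p = 0.0144). Ighm, the immunoglobulin M heavy chain, fell from 19.7 ± 3.55 to 10.4 ± 1.77 CPM (-0.92, SE 0.22, edgeR adjusted p = 0.0173), and Cd79b (-2.12), Ighd (-1.95) and Igkc (-1.74) fell too. Corrected for transcript length, the median was -0.94 (camera adjusted p = 0.0064; adjusted p = 0.869 with an estimated correlation) and Cd79a was the member past the threshold. The call of Cd79a ended without anti-IgG library 3 or anti-PD-1 library 1 (edgeR adjusted p = 0.0675 and 0.051), and that of Ighm without anti-IgG library 2 or 3 or anti-PD-1 library 1 (0.0538 to 0.0891). With the stricter count filter the list did not pass (camera adjusted p = 0.0572).

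Myeloid lists gave no list-wide call. Among 20 macrophage and monocyte genes 1 rose, 3 fell and 16 did not pass, with the same counts adjusted over the list alone (median -0.35, camera adjusted p = 0.613; 0.00963 without anti-IgG library 1). Adgre1, the macrophage surface protein F4/80, rose from 12.4 ± 3.38 to 24.3 ± 3.81 CPM (log2 fold change 0.97, SE 0.24), while the complement genes C1qa (-1.56), C1qb (-0.91) and C1qc (-1.10, SE 0.29) fell (edgeR adjusted p = 0.0185 for Adgre1 and 0.0249 to 0.0373 for the others). The 3 complement calls ended with the transcript length trend removed, where Adgre1 kept a log2 fold change of 1.06. Adgre1 lost its call without anti-IgG library 2 or anti-PD-1 library 1 or 3 (edgeR adjusted p from 0.0543 to 0.0871). C1qc lost it without any 1 library other than anti-IgG library 1 (0.0516 to 0.106) and by limma-trend on FPKM (0.0515 to 0.0567). Of 12 neutrophil genes 4 were tested and 0 changed, with S100a8 at 0.89 (SE 1.24) and Mmp9 at 0.49 (SE 0.78) and a list median of 0.15 (camera adjusted p = 0.984). None of 15 tested cytokine and chemokine genes (21 listed) changed by edgeR (median -0.01, mean 0.18, camera direction up, adjusted p = 0.984). Cxcl5, a neutrophil-attracting chemokine, had the largest value, 3.59 with an SE of 1.39 (edgeR adjusted p = 0.111, 0.0428 without anti-PD-1 library 3 and 0.0491 with robust=FALSE). It rested on anti-PD-1 library 1: Cxcl5 had 295, 17 and 8 reads in the anti-PD-1 libraries and 7, 11 and 7 in the anti-IgG libraries, and without that library its value was 0.55 (edgeR adjusted p = 0.636). Cxcl12 was at 0.48 (SE 0.23).

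Matrix genes were higher as a list by a narrow margin. Of 25 extracellular matrix and fibrosis genes 3 rose, 0 fell and 22 did not pass, and 2 rose when adjusted over the list alone. The median was 0.57 (camera adjusted p = 0.0495; adjusted p = 0.996 with an estimated correlation). Col8a1, a short-chain collagen of vessels and scars, rose from 96.5 ± 21.1 to 277 ± 147 CPM (log2 fold change 1.52, SE 0.35, edgeR adjusted p = 0.0183), Col12a1 from 9.77 ± 5.51 to 44.4 ± 22.5 CPM (2.18, SE 0.53, edgeR adjusted p = 0.0284), and Tgfb2 by 0.83 on the log2 scale. The textbook fibrosis markers did not pass: Col1a1 stood at 474 ± 197 against 280 ± 139 CPM (0.76, SE 0.42), Col3a1 at 891 ± 365 against 618 ± 224 CPM (0.53, SE 0.37) and Postn at 849 ± 388 against 567 ± 335 CPM (0.58, SE 0.55). Without the count filter Col1a1 passed (edgeR adjusted p = 0.0124) and Col12a1 did not (0.108). The list's call ended without anti-IgG library 1 (median 0.26, camera adjusted p = 0.564) and without anti-PD-1 library 3 (0.28, 0.475). It also ended with RLE scaling (camera adjusted p = 0.0565), with the stricter filter (0.0623), without mitochondrially encoded and haemoglobin genes (0.0526) and with the gene length (median 0.45, 0.103) or transcript length trend removed (median 0.39, 0.171). Col8a1 lost its call without anti-IgG library 2 or anti-PD-1 library 1 (edgeR adjusted p = 0.0961 and 0.0505). Col12a1 lost it without anti-IgG library 2 or anti-PD-1 library 1 or 3 (0.0633 to 0.115), and all 3 calls ended with the transcript length trend removed. The log2 fold changes there were 1.09 for Col8a1, 1.32 for Col12a1 and 0.56 for Tgfb2.

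The hypertrophy and fetal gene programme moved in both directions. Of 15 genes 2 rose, 2 fell and 11 did not pass, with 2 rises and 3 falls adjusted over the list alone (median 0.29, camera adjusted p = 0.805). Xirp2, an actin-binding protein of the intercalated disc, rose from 1187 ± 245 to 3727 ± 1385 CPM (log2 fold change 1.65, SE 0.31, edgeR adjusted p = 0.00811), and Fhl1, a LIM-domain protein of the sarcomere, from 219 ± 48.5 to 492 ± 182 CPM (1.17, SE 0.30, edgeR adjusted p = 0.0226), while Nmrk2 (-1.07) and Myh7b (-1.24) fell. The natriuretic peptide genes did not pass: Nppa stood at 135 ± 20.2 against 457 ± 310 CPM (-1.75, SE 0.55, edgeR adjusted p = 0.0573) and Nppb at 540 ± 143 against 892 ± 291 CPM (-0.72, SE 0.29, edgeR adjusted p = 0.0924). The myosin heavy chain genes Myh7 (0.36, SE 0.66) and Myh6 (0.04, SE 0.33) did not pass either. These values depended on anti-IgG library 1, where Nppa was at 123 CPM and Myh7 at 1628 CPM against 410 and 284 CPM for Myh7 in anti-IgG libraries 2 and 3. Without it Nppa, Nppb and Myh7 were past the threshold (edgeR adjusted p = 0.00177, 0.0351 and 0.0161). Nppa also passed with robust=FALSE (0.031), and Nppb by DESeq2 (0.0485) and without the count filter (0.0297). Fhl1 lost its call without anti-IgG library 2 or 3 or anti-PD-1 library 1 or 3 (0.0507 to 0.0933) and Xirp2 with the transcript length trend removed (0.138).

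Among 22 genes of contraction and calcium handling, 3 rose, 5 fell and 14 did not pass, with 6 rises and 6 falls adjusted over the list alone (median -0.05, mean 0.03, camera direction up, adjusted p = 0.805). Slc8a1 and the ryanodine receptor gene Ryr2 (1.39, SE 0.24, edgeR adjusted p = 0.00644) were among those that rose. The 5 that fell encode sarcomere proteins: Tnnt2 (-1.22), Tnni3 (-1.35), Tnnc1 (-1.52), Tpm1 (-1.18) and Myl2 (-1.87). Slc8a1 remained past the threshold by edgeR with the transcript length trend removed, and Ryr2 and these 5 did not. With that correction Ryr2 was at 0.62, Tnnt2 at -0.63, Tnni3 at -0.53, Tnnc1 at -0.65, Tpm1 at -1.08 and Myl2 at -1.11.

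Among the energy metabolism lists, oxidative phosphorylation passed on the counts as deposited, and fatty acid oxidation and glycolysis did not. Differences between these lists were not tested. Of 23 oxidative phosphorylation genes 11 fell, 0 rose and 12 did not pass, with 13 falls adjusted over the list alone and a median of -0.66 (camera adjusted p = 2.19e-06; adjusted p = 0.996 with an estimated correlation). Cox6c fell from 657 ± 57.7 to 152 ± 46.4 CPM (log2 fold change -2.12, SE 0.26) and Cox5b from 241 ± 101 to 54.9 ± 20.3 CPM (-2.13, SE 0.37; edgeR adjusted p = 0.00224 and 0.00802); both encode cytochrome c oxidase subunits. After correction for transcript length the list's median was -0.12 and its call ended (camera adjusted p = 0.164), while Cox6c (-1.06), Cox5b (-1.28) and Cox7a1 (-1.82) remained past the threshold. Of 22 fatty acid oxidation genes 2 rose, 2 fell and 18 did not pass, with the same counts adjusted over the list alone (median -0.10, mean 0.03, camera direction down, adjusted p = 0.984): Ppara and Acsl1 (0.86) rose, and Fabp3 (-1.44) and Eci1 (-0.91, SE 0.24) fell. Of 19 glycolysis genes 1 fell, also when adjusted over the list alone, and 18 did not pass (median 0.10, mean -0.03, camera direction down, adjusted p = 0.984). It was the muscle phosphoglycerate mutase Pgam2 (-1.42, SE 0.34, edgeR adjusted p = 0.0182), and Aldoa stood at -0.75 (SE 0.25, edgeR adjusted p = 0.054). The calls of Eci1 and Pgam2 ended without anti-IgG library 2 or 3 or anti-PD-1 library 1 or 3 (edgeR adjusted p from 0.0512 to 0.10) and with the transcript length trend removed (0.418 and 0.138). Aldoa passed without anti-IgG library 1 (0.034), with upper quartile scaling (0.0311), without the count filter (0.0302), with the stricter filter (0.0489) and by DESeq2 (0.0106).

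Ribosomal protein genes had the strongest list result. Of 22 tested, 17 fell, 0 rose and 5 did not pass, with 18 falls adjusted over the list alone, and the median was -0.82 (camera adjusted p = 3.5e-10; adjusted p = 0.996 with an estimated correlation; fry adjusted p = 0.0668). Rpl37 fell from 96.2 ± 8.69 to 37.9 ± 2.40 CPM (log2 fold change -1.35, SE 0.17, edgeR adjusted p = 0.0024). These genes are short, and many have processed pseudogenes that can share reads. Corrected for transcript length, the median was -0.056 (camera adjusted p = 0.315), 1 of the 22 was past the threshold, and the call of Rpl37 ended (edgeR adjusted p = 0.121).

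**Figure D3:**
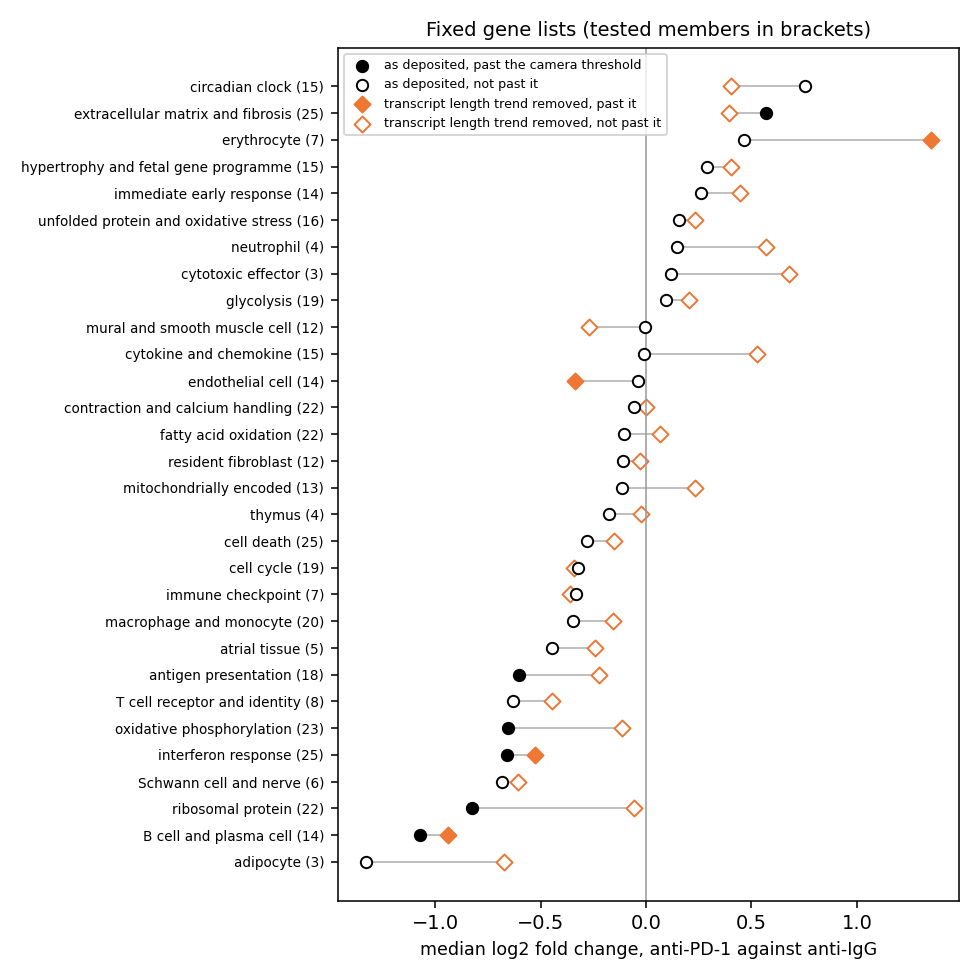
Median log2 fold change of each fixed gene list with at least 3 tested members (x axis; positive is higher with anti-PD-1), from the counts as deposited (circles) and with each library's transcript length trend removed (diamonds); filled symbols passed camera with the preset correlation. The ribosomal protein list moves from -0.82 to -0.056 and the interferon response list from -0.66 to -0.53.

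Stress and death genes showed scattered falls. Of 25 cell death genes 3 fell, 0 rose and 22 did not pass, with 2 falls adjusted over the list alone (median -0.28, camera adjusted p = 0.451). Bax, a mitochondrial effector of apoptosis, fell from 19.5 ± 6.77 to 6.83 ± 1.79 CPM (log2 fold change -1.51, SE 0.30, edgeR adjusted p = 0.00991). Gsdmd, the pore-forming protein of pyroptosis, fell from 12.2 ± 3.07 to 5.33 ± 1.01 CPM (-1.19, SE 0.26, edgeR adjusted p = 0.0126), and Pycard, an inflammasome adaptor, had a log2 fold change of -0.90. Of 16 tested genes of the unfolded protein and oxidative stress list (17 listed) 1 fell, also adjusted over the list alone, Ddit3 (-1.07, SE 0.24, edgeR adjusted p = 0.0153), and Atf4 stood at -0.85 (SE 0.31, edgeR adjusted p = 0.0749; list median 0.16, mean -0.06, camera direction up, adjusted p = 0.984). None of 19 cell cycle genes changed by edgeR, with Birc5 at -1.39 (SE 0.67) and Plk1 at -1.20 (SE 0.75), and the list had a median of -0.32 (camera adjusted p = 0.805). The calls of Bax, Gsdmd, Pycard and Ddit3 ended with the transcript length trend removed (edgeR adjusted p from 0.0933 to 0.578). That of Bax ended without anti-IgG library 2 (0.0556), that of Gsdmd without anti-IgG library 2 or anti-PD-1 library 1 (0.0712 and 0.0523), and that of Ddit3 without anti-IgG library 2 or anti-PD-1 library 1 or 3 (0.0512 to 0.0644). Without anti-IgG library 1, Atf4 (0.0129) and Birc5 (0.034) passed, and so did the cell cycle list (median -0.81, camera adjusted p = 0.02). Without the count filter Atf4 (edgeR adjusted p = 0.00128) and Birc5 (0.0428) passed, and Atf4 also by DESeq2 (0.0319).

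Markers of the other cells of the ventricle moved in opposite directions within lists. Of 14 endothelial genes 1 rose, 3 fell and 10 did not pass, with 1 rise and 5 falls adjusted over the list alone (median -0.04, camera adjusted p = 0.615). Egfl7, a matrix protein secreted by endothelium, fell from 110 ± 25.2 to 29.4 ± 6.67 CPM (log2 fold change -1.90, SE 0.23, edgeR adjusted p = 0.00224), Cldn5 (-1.03) and Esam (-0.82) fell, and Vwf, von Willebrand factor, rose from 46.3 ± 6.63 to 102 ± 27.2 CPM (1.14, SE 0.22, edgeR adjusted p = 0.00883). Corrected for transcript length, Egfl7 was at -1.53 and Vwf at 1.07, both past the threshold. The endothelial list then passed as lower (median -0.34, camera adjusted p = 0.0141, fry adjusted p = 0.0111; adjusted p = 0.823 with an estimated correlation). Of 12 mural and smooth muscle cell genes 1 rose, 2 fell and 9 did not pass, with the same counts adjusted over the list alone (median 0.00, mean 0.01, camera direction up, adjusted p = 0.984): Notch3 rose (1.06, SE 0.20) and Vtn (-0.86, SE 0.17) and Kcnj8 (-0.64) fell (edgeR adjusted p = 0.00864, 0.00927 and 0.0242). None of 12 resident fibroblast genes changed by edgeR, with Pdgfra at 0.49 and Tcf21 at -0.53 (median -0.11, camera adjusted p = 0.871). Without anti-IgG library 2 the calls of Vwf (edgeR adjusted p = 0.0558), Notch3 (0.058) and Vtn (0.0503) ended, and with the transcript length trend removed those of Notch3 (0.11), Vtn (0.278), Cldn5, Esam and Kcnj8.

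Lists that stand for other tissue gave few calls. The atrial list had 5 tested members and 0 changed by edgeR (median -0.45, camera adjusted p = 0.805), with Myl4 at -1.29 and Kcna5 at -0.45. Myl4 was past the threshold without anti-IgG library 1 (edgeR adjusted p = 0.0341). The adipocyte list had 3 and 0 (median -1.33, camera adjusted p = 0.613), with Cidea at -0.54 and Pnpla3 at -1.36. The thymus list had 4 and 0 (median -0.18, camera adjusted p = 0.871), with Tcf7 at -0.81 and Cd1d1 at -0.44. Without the count filter the adipocyte list passed as lower (camera adjusted p = 0.0452). In the erythrocyte list 1 of 7 tested members rose, also adjusted over the list alone: Slc4a1, the anion exchanger of red cells, with 12, 22 and 55 reads against 5, 1 and 5 (log2 fold change 2.92, SE 0.72, edgeR adjusted p = 0.0198). Alas2 stood at 1.02 (SE 0.52; 0.046 by DESeq2 and 0.0244 by edgeR without anti-PD-1 library 1). The list had a median of 0.46 (camera adjusted p = 0.615, and 5.89e-04 without anti-PD-1 library 1). Corrected for transcript length, that list passed as higher (median 1.35, camera adjusted p = 0.0346; adjusted p = 0.869 with an estimated correlation). In the Schwann cell and nerve list 1 of 6 tested members rose, Scn7a (0.84, SE 0.24), and 1 fell, Sox10 (-1.34, SE 0.41; edgeR adjusted p = 0.0308 and 0.0419), the same adjusted over the list alone. That list had a median of -0.68 (camera adjusted p = 0.613). The skeletal muscle and mesothelium lists had 1 tested member each, Myl1 (-0.90) and Wt1 (-0.32), which did not pass, and so were not tested as lists. Slc4a1 lost its call without anti-IgG library 2 or 3 or anti-PD-1 library 3 (edgeR adjusted p from 0.0559 to 0.0919) and by limma-trend on log2(FPKM + 1) (0.0837). Scn7a lost it without anti-IgG library 2 or 3 or anti-PD-1 library 1 (0.0814 to 0.119), Sox10 without any 1 library other than anti-IgG library 1 (0.0743 to 0.139) or without the count filter (0.0568), and all 3 with the transcript length trend removed (0.0579 to 0.538). The log2 fold changes there were 2.62 for Slc4a1, -1.285 for Sox10 and 0.22 for Scn7a. Myl1 was past the threshold without anti-IgG library 1 (0.00404) and without the count filter (0.00451).

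The lists for handling, hour of collection and mitochondrially encoded transcripts did not pass on the counts as deposited. None of 14 immediate early genes changed by edgeR (median 0.26, camera adjusted p = 0.738; Hspa1b at 0.95 and Zfp36 at -0.62). Zfp36 was past the threshold without anti-IgG library 1 (edgeR adjusted p = 0.0225) and Hspa1b without the count filter (0.0273). None of the 13 mitochondrially encoded genes changed by edgeR, with mt-Nd5 at 0.82 (SE 0.31, adjusted p = 0.0827) and mt-Co3 at -0.75 (SE 0.29, adjusted p = 0.0852; 0.0273 without anti-IgG library 1), and the list had a median of -0.11 (camera adjusted p = 0.871). With the gene length trend removed its median turned to 0.59 and it passed as higher by camera (adjusted p = 0.00759) but not by fry (0.219). By DESeq2 mt-Nd5 (0.00322) and mt-Co3 (0.0253) passed, as they did by edgeR without the count filter (0.0392 each). With the transcript length trend removed mt-Nd5 was past the threshold (edgeR adjusted p = 0.0394), but that correction did not use its own length. With the gene length trend removed mt-Nd5 was at 1.31 (edgeR adjusted p = 0.0215). In the circadian clock list 2 of 15 genes rose, Clock (0.83, SE 0.24) and Bhlhe41 (0.64, SE 0.20; edgeR adjusted p = 0.0335 and 0.0415), and 0 when adjusted over the list alone (median 0.76, camera adjusted p = 0.451). Clock lost its call without anti-IgG library 2 or 3 or anti-PD-1 library 1 or 3 (0.0907 to 0.153), Bhlhe41 without any 1 of the 6 libraries (0.0653 to 0.106) or with upper quartile scaling (0.068), and both with the transcript length trend removed (0.622 and 0.51). By limma-trend on log2(FPKM + 1) neither passed (0.0533 each). Anti-PD-1 library 2 stood apart in these genes: Arntl was at 3.27 CPM against 22.2 to 31.4 CPM in the other 5 libraries, and Dbp at 58.6 CPM against 1.25 to 14.8 CPM.

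**Figure D4:**
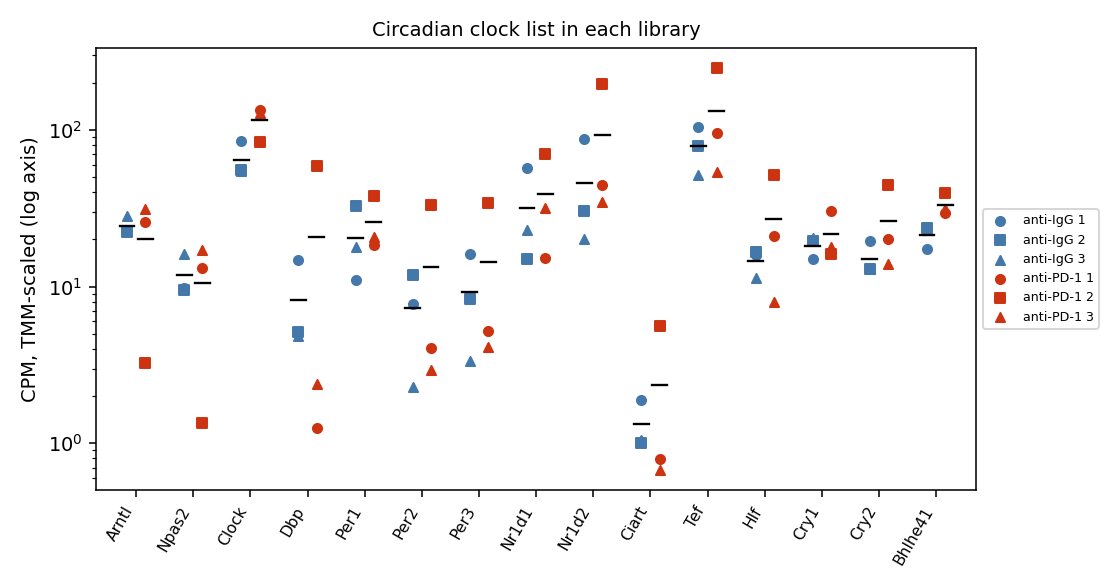
CPM on a log axis of the 15 circadian clock genes; each point is 1 library and black bars are means over 3 libraries. Anti-PD-1 library 2 (red squares) lies above the other 5 libraries in 11 genes and below them in 2, Arntl and Npas2.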

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

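The 4 trend corrections were chosen after the data were seen; the others were fixed beforehand. With all 6 libraries, the number of changed genes lay between 2719 and 3832 over the other scalings, filters, tests and gene sets, and at 4663 with an adjusted p under 0.1, against 3118. It was 1424 when an absolute log2 fold change of at least 1 was also required, a stricter criterion by construction. It was 1526 with the gene length trend removed, 756 with the transcript length trend removed and 882 with that and the GC trend removed. With the GC trend alone removed it was 3388. The fold changes followed length, and its trend is removed whatever its origin, so the lower numbers do not show where that trend came from. The share of changed genes that rose was 48.9%, and 36.8% with upper quartile scaling, 58.0% with the GC trend removed and 59.4% with the transcript length trend removed. Leaving out 1 library gave 532 to 3646 genes, fewest without anti-IgG library 2 (532), anti-PD-1 library 1 (969), anti-IgG library 3 (1564) and anti-PD-1 library 3 (1766); 5 libraries test with less power by construction. Against 6 fixed lists past the threshold, 4 to 7 passed under the other scalings, filters and corrections and 5 to 7 without 1 library, but 0 by camera with an estimated correlation and 0 by fry, which both allow for correlation between genes by construction. With the transcript length trend removed 4 passed, but only 2 of these were among the 6. The others were the endothelial and erythrocyte lists. The mitochondrially encoded list turned from lower, not past the threshold, to higher and past it with the gene length trend removed (median 0.59, camera adjusted p = 0.00759, but fry adjusted p = 0.219), and the cause was not tested.

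Of the 53 genes set by the naming rule that were past the threshold, 43 kept their call in all 12 other analyses fixed beforehand with 6 libraries, 23 without each library in turn, 35 with the gene length trend removed and 24 with the transcript length trend removed; 18 kept it in all of these. No gene of that rule turned direction in an alternative where either value was past the threshold. The rank correlation of the log2 fold change with gene length was 0.43 to 0.56 in every analysis fixed beforehand.

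The replicate numbers are shared between the groups, and whether they pair the samples could not be decided from the data. Deviations from the group means correlated at 0.12, -0.14 and 0.21 between libraries of the same number. Of the 6 libraries, 3 correlated best with their own number. With the replicate block 3367 genes were past the threshold and 6 lists. Depth limits the genes of few reads: Pdcd1, Gzmb and Prf1 had 6 to 20 reads per group.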

Other observations

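The anti-IgG libraries differed from one another in the cell cycle and matrix lists. In anti-IgG library 1 the cell cycle list lay at a median of -1.28 on the log2 scale against the 6-library mean, and at 0.98 and 0.59 in anti-IgG libraries 2 and 3; the matrix and fibrosis list lay at -1.01, -0.04 and 0.20. Postn, a matrix protein of activated fibroblasts, stood at 185 CPM there against 813 and 702 CPM. The anti-PD-1 libraries had cell cycle medians of -0.32, -0.66 and 0.66 and matrix medians of 0.37, -0.33 and 1.00, so each group spanned a range on both lists.

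Of the unannotated transcripts, 140 were tested, and 12 rose and 22 fell with anti-PD-1. The most expressed of the 12, chosen after its values were seen, lies on chromosome 14 from 32115303 to 32120673 in mm10. It rose from 81.4 to 514 mean CPM (log2 fold change 2.66, SE 0.27, edgeR adjusted p = 0.00123). Its log2 fold change was 3.02 with the transcript length trend removed, a correction that did not use its own length. With the gene length trend removed, which did, it was 2.57.

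Of the tests reported in the following paragraphs, those that use transcript length and the splits of the samples were chosen only after the result was seen, and so was the use of fry and of quartiles to allow for spread, and of both length corrections for the macrophage markers. The 10 splits of the 6 libraries into 3 and 3 are too few to give a share under 0.05; the real split was 1 of the 10, with 3118 genes past the threshold, and the highest of the others gave 0 by edgeR. At an unadjusted p under 0.05 the real split had 5457 genes and the highest other 1155.

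The lower ribosomal protein and oxidative phosphorylation lists may follow from the length trend rather than from these pathways. The values argue against GC content as the cause for the ribosomal list: with its trend removed the median was still -0.75, past the threshold by camera with the preset correlation and by fry, though not by camera with an estimated correlation (adjusted p = 0.493). For oxidative phosphorylation it was -0.55 (quartiles -1.09 to -0.275), past the threshold by camera with the preset correlation, which met the bound set beforehand. These values argue against GC content as the cause of that whole list's fall too. By fry the list did not pass (adjusted p = 0.116), but it did not pass before the correction either (0.091). With an estimated correlation its camera adjusted p was 0.90. Removing the trend on the authors' gene length left medians of -0.46 for the ribosomal list (camera adjusted p = 5.06e-05, fry 0.0254) and -0.38 for oxidative phosphorylation (camera 0.000141, fry 0.219). With an estimated correlation neither passed camera (adjusted p = 0.335 and 0.954). With the preset correlation both lists stayed past the camera threshold there, an outcome set beforehand to speak against length. That bound may not decide the question, because those lengths can misstate short transcripts (3567 against 364 bp for Cox6c). How often they do so in these lists was not tested. With the transcript length trend removed the ribosomal median went from -0.82 (quartiles -1.14 to -0.61) to -0.056 (-0.47 to 0.15) and the oxidative phosphorylation median from -0.66 (-1.17 to -0.36) to -0.12 (-0.36 to 0.10), and both calls ended because the medians moved close to 0. Whether the length trend itself came from RNA integrity or library preparation or from the antibody cannot be told apart here, since the trend coincides with the groups.

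The lower interferon response list may be separate from length. Its median was -0.57 with the gene length trend removed and -0.53 with the transcript length trend removed. Both passed by camera with the preset correlation, but not with an estimated correlation (adjusted p = 0.954 and 0.869) or by fry (0.219 and 0.254). The gene length value met a bound set beforehand against length. It did so by camera alone and on lengths that can misstate short transcripts, so a part played by length stays open. The antigen presentation list, at -0.27 and -0.22 after the same corrections, no longer passed, and length cannot be told apart from another cause because these medians lie between the bounds set for either outcome. If fewer macrophages and monocytes were the cause, their markers were to fall by at least as much as the interferon genes. With the gene length trend removed those markers had a median of -0.046 (quartiles -0.17 to 0.10), which met the outcome set beforehand against this explanation. With the transcript length trend removed, a check added later, it was -0.15 (-0.27 to 0.05), below the value set in that outcome. The markers' median was -0.35 before any correction. Without anti-IgG library 1 it was -0.55 (camera adjusted p = 0.00963), where the interferon list was at -0.85. In each of these settings the markers fell less than the interferon genes. A part played by fewer macrophages and monocytes cannot be told apart. Whether PD-1 blockade itself lowered interferon genes was not tested.

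Anti-PD-1 library 2 may have been collected at another hour than the others. This was noticed in Arntl. Then, before their values were seen, 5 genes of the opposite phase (Dbp, Per3, Nr1d1, Ciart and Tef) were named that were to lie above the other 5 libraries if another hour of tissue collection was the cause, and 5 did: Per3 was at 33.9 against at most 16.1 CPM and Tef at 249 against at most 105 CPM. In all, 13 of 15 clock genes lay outside the range of the other 5 libraries there, against 2 to 5 in each other library, while 33.4% of all tested genes did. No collection time is in the labels, and no biological explanation was tested. Without this library 2507 genes changed.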
